A study of Mus musculus with 8 samples.

How the data were processed

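Gene expression was measured in whole lungs of 8 male chimeric mice aged 22 weeks, harvested 72 hours after diphtheria toxin. Each chimera had received bone marrow from a donor, and donor and recipient were either wild type or LysM-DTR, a strain in which the lysozyme M promoter drives the diphtheria toxin receptor so that the toxin kills cells that express it. Groups are named by donor and then recipient: LL has LysM-DTR marrow in a LysM-DTR recipient, WL wild-type marrow in a LysM-DTR recipient, LW LysM-DTR marrow in a wild-type recipient, and WW is wild type on both sides. Each of the 4 groups had 2 mice, with 1 array per mouse.

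Total RNA was labelled with Cy3 and hybridised to one-colour Agilent arrays of 62976 spots. The deposited per-array files hold intensity values extracted with Agilent Feature Extraction 11.5.1.1, per the file headers after background subtraction and detrending within the array but with no scaling between arrays. The deposited series table holds log2 values, which were compared with the array files and found to be the log2 of the processed signal minus a constant per array that sets the 75th percentile to 0, with no centring per gene. Probe positions are those of the array annotation on mm9. All 8 arrays lay on 1 slide and were read in 1 scan; LL and WL occupied one column of the slide and LW and WW the other, and in each column the LysM-DTR donor group held places 1 and 2 and the wild-type donor group places 3 and 4.

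Of the 59305 non-control spots, those marked as non-uniform were left out (0 to 4 per array). The processed intensities of the spots of a probe were averaged, which gave 56605 probes for 37074 gene names. These averages were taken to log2, and each array's 75th percentile over the probes was subtracted. Probes were kept when they were well above background on both arrays of at least 1 group (39602 probes), and each gene was represented by its probe with the highest mean over the 8 arrays, which left 25830 genes. Of these, 16492 matched a symbol or accession of a RefSeq table on GRCm38.p6, used for names only; 796 of them carry another symbol today, and names are printed as the array gives them. No spot was saturated.

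Genes were tested with limma 3.58.1 in R 4.3.3: a model of 4 group means on all 8 arrays, 4 residual degrees of freedom, 2.19 prior degrees of freedom, and Benjamini-Hochberg adjustment over all genes within a comparison, called at an adjusted p under 0.05. Comparisons were WL, LW and LL against WW, WL against LW, LL against WL, the recipient and donor genotypes averaged over the other side, and the donor by recipient interaction. Changes are given as log2 differences with their standard error (SE). For a gene not above background on either array of a group the fitted change is no bound, so the lowest fold that the background allows is given instead. A total of 41 lists of marker and pathway genes (823 entries), written before the data were examined, were tested with camera at a preset correlation of 0.01 between genes; camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Figures were drawn with Python 3.11.15.

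Genes are named by a rule also written before the data were examined: in each comparison with WW the 10 higher and 10 lower called genes with the largest change whose groups do not overlap and that were above background on all their arrays, and the 3 with the largest bound on either side among those at background in one group; 5 higher and 5 lower in the other comparisons; up to 4 called members of each described list, or the 2 with the smallest p where none was called; all called genes where fewer than 5 were; and a fixed set that includes Lyz2, Hbegf, surfactant proteins and cell markers. Predicted genes, clones and receptor segments are counted but not named, except where fewer than 5 genes were called. Any gene outside the rule is said to have been chosen after its values were seen.

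On simulated data for LL against WW (25829 genes), the test called 8, 31, 41 and 43 of 50 genes changed by 1, 2, 3 and 4 on the log2 scale, and 7 of 25593 unchanged genes. The simulation gave a gene the same spread in every group, whereas the real WL mice differed more than the other pairs. These values therefore do not measure how often the test misses or wrongly calls genes on the real arrays. The settings varied were, as chosen before the data were examined, another background correction (normexp with an offset of 50), quantile normalisation, a percentile over probes detected on all arrays, no filter or a stricter filter, a fold threshold, the mean of a gene's probes, the deposited series table, the replicate number as a block, another variance model, the compared arrays alone, and leaving out each array. Further settings were chosen after seeing the data: leaving out both WL arrays, and leaving out population outlier spots. Leaving out 1 array leaves 1 mouse in its group, whose spread is then taken from the other groups. Counts from such fits measure no spread between the mice of that group. A block for the slide was planned but not run, since there was 1 slide.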

Results

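The series profiled lungs of bone marrow chimeras after diphtheria toxin, as a model of acute lung injury in which the toxin can reach lysozyme M expressing cells of the marrow, of the recipient, or of both. Lysozyme M (Lyz2) is made by macrophages, monocytes and neutrophils, and in the lung also by alveolar type 2 cells, the epithelial cells that secrete surfactant. Its title names growth factors for repair and biomarkers of injury as the aim. There were 8 arrays, 2 mice in each of LL, WL, LW and WW. The 75th percentile of the signal ran from 208.6 to 324.4 intensity units, and 66.3 to 72.3% of the non-control spots were well above background. The recipient genotype coincided with the column of the slide, and the donor genotype with the place along it (1 and 2 for LL and LW, 3 and 4 for WL and WW), so genotype and position cannot be told apart in a comparison of 2 groups or in the averages over donor or recipient. In the interaction an effect of place that is equal in both columns cancels.

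Both LL mice, both LW mice and both WW mice gave like profiles, with a Pearson r across genes of 0.99, 0.99 and 0.992 within the pairs (genes are not independent replicates). The WL mice did not, at r = 0.96. WL replicate 1 had r = 0.993 with the mean of the LW and WW arrays and 0.959 with the LL mean, and WL replicate 2 had 0.957 and 0.974. For WL the values of the single mice are therefore given for the lists that differ and for several genes.

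**Figure D1:**
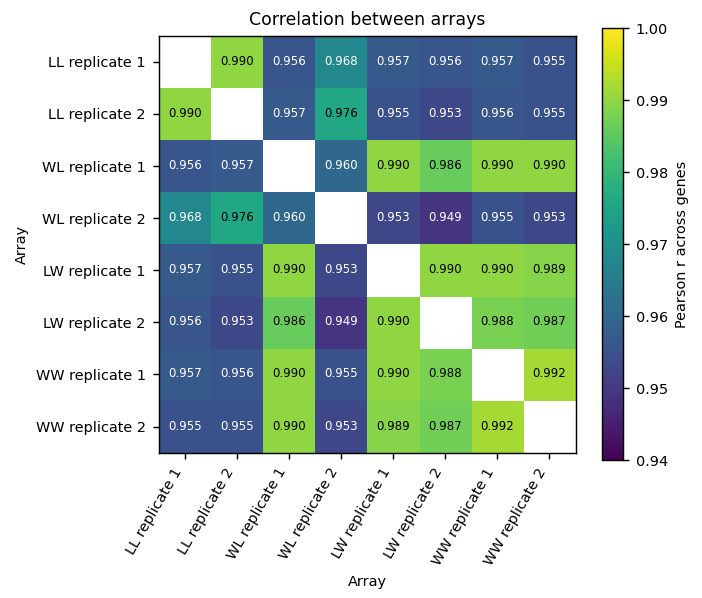
Pearson correlation across genes between each pair of the 8 arrays, with arrays on both axes and r as colour and number. The LL, LW and WW pairs stand at 0.99 or above, and the WL pair at 0.96.

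The comparison of LL with WW sets mice whose marrow and recipient both carried the receptor against wild-type chimeras, all after the toxin. No array is of mice without toxin, so killing by the toxin cannot be told apart from other effects of the genotype. Genes made by macrophages and monocytes were among those lower in LL. Lyz2 itself fell by 4.27 on the log2 scale (SE 0.408, n = 2 mice per group, adjusted p = 0.0122), from a mean of 9.07 ± 0.02 (SD) in WW to 4.80 ± 0.19 in LL. Its probe lies on chromosome 10, 116714450 to 116714509 (mm9). The close copy Lyz1 fell by 4.57 (SE 0.478); how far each probe also reads the other gene was not measured. The complement subunit C1qa fell by 4.73 (SE 0.236, adjusted p = 0.00612), from 0.89 ± 0.14 in WW to -3.84 ± 0.19 in LL, and its neighbours on chromosome 4, C1qc and C1qb, fell by 4.88 (SE 0.276) and 3.35 (SE 0.239). Clec7a, the beta-glucan receptor dectin-1, fell by 6.01 (SE 0.363), and the monocyte chemokine receptors Ccr2 and Cx3cr1 fell by 5.06 (SE 0.34) and 6.41 (SE 0.347).

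The fall took in several lists of blood and immune cells. Of 23 measured genes of monocytes and recruited macrophages, 9 fell, none rose and 14 did not pass, Ms4a7 among the lowest at -5.84 (SE 0.212, adjusted p = 0.00271); adjusted over the list alone, 12 fell and 3 rose, so the list held genes of both directions. The list passed camera (median -0.64, adjusted p = 5.36e-05; adjusted p = 0.526 with an estimated correlation). Of 20 alveolar macrophage genes 4 fell: the lectin Siglecf, at least 16.4-fold, the integrin Itgax, by 4.52, the eosinophil-type ribonuclease Ear2, by 3.34, and the mannose receptor Mrc1, by 2.38. Adjusted over the list alone it was 12 of 20 (median -1.68, camera adjusted p = 2.51e-06, adjusted p = 0.526 with an estimated correlation), while the scavenger receptor Marco did not pass (-1.50, SE 1.496). Of 16 dendritic cell genes 6 fell, including Cd209a, at least 30.9-fold, Cd207, at least 9.22-fold, and Clec9a, by 4.14 (median -1.46, 10 adjusted over the list alone, camera adjusted p = 6.23e-06, adjusted p = 0.406 with an estimated correlation). Platelet genes were the lowest list, with 9 of 12 members down. The chemokine Ppbp fell by 7.43 (SE 0.488, adjusted p = 0.00669), the glycoproteins Gp9 and Gp1ba were at least 52.4-fold and 8.43-fold lower, and the receptor Clec1b fell by 4.40 (list median -2.83, 10 lower and 1 higher adjusted over the list alone, camera adjusted p = 8.17e-09, adjusted p = 0.406 with an estimated correlation).

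Lymphocyte lists were lower as well. Among 13 NK cell genes 4 fell, with the receptors Klra4 by 4.22 and Klra8 by 3.83 and the death ligand Fasl by 2.25; 11 fell adjusted over the list alone (median -2.63, camera adjusted p = 1.48e-08). Among 18 T cell genes Cd8a fell by 2.67 and the interleukin 7 receptor Il7r by 1.66, and 14 fell adjusted over the list alone (median -2.04, camera adjusted p = 4.33e-09). None of 15 B cell genes passed over all genes, 11 did adjusted over the list alone, and the B cell gene Fcrla stood at -2.86 (list median -2.30, camera adjusted p = 1.98e-06). With an estimated correlation the adjusted p was 0.526, 0.542 and 0.549 for the NK, T and B cell lists. Neutrophil genes did not move one way: none of 22 passed, and 3 were higher and 3 lower adjusted over the list alone (list adjusted p = 0.725). The neutrophil marker Ly6g was at 1.57 (adjusted p = 0.0782), the chemokine receptor Cxcr2 at -3.30 (adjusted p = 0.0799) and S100a8 at -0.19. The list mean was -0.53 in LL replicate 1 and 0.97 in LL replicate 2. Of the antigen presentation genes 4 fell, H2-Eb1 by 3.15, H2-Aa by 2.97, H2-DMa by 2.16 and H2-DMb1 by 2.12, while the interferon gamma and MHC class II list did not pass (adjusted p = 0.138). Of the genes named so far, Cx3cr1, Ms4a7, Clec9a, Ppbp, Klra4, Fasl and Cd8a were above background on 1 of the 2 LL arrays, so the size of their fall rests in part on background.

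Genes of cell division rose in LL. Of 36 cell cycle genes 21 rose and none fell (28 adjusted over the list alone, and all 36 were above 0). The mitotic kinase Cdk1 rose by 2.58 (SE 0.441, adjusted p = 0.0409), its partner cyclin Ccnb2 by 1.99 (SE 0.226), the spindle factor Tpx2 by 1.93 and the kinase Plk1 by 1.91. The list median was 1.19 and its camera adjusted p = 2.02e-18, with adjusted p = 0.518 with an estimated correlation and 0.0131 with fry. Other dividing-cell genes among the largest rises were the kinetochore gene Spc24 (2.80, SE 0.38), Ect2 (2.45), Cdca3 (2.35) and Iqgap3 (2.30), and Hist1h3g and Fam83d were at least 10.97-fold and 4.93-fold higher. Prg4, which codes for lubricin, rose by 3.65 (SE 0.621, adjusted p = 0.0407), the steroid dehydrogenase Akr1c14 by 2.64 and the kinase Pak6 by 2.33, and Lypd8, absent from WW above background, was at least 3.98-fold higher.

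Genes of the lung epithelium changed in part. In whole lung a change in the shares of cells cannot be told apart from a change within cells. Of 20 alveolar type 2 cell genes 1, Lyz1, fell over all genes and 11 did adjusted over the list alone; surfactant protein C (Sftpc) was at -2.10 (SE 0.587, adjusted p = 0.112), whereas Sftpb and Sftpd were at -0.25 each. That list passed camera (median -1.28, adjusted p = 4.96e-07; adjusted p = 0.549 with an estimated correlation). Alveolar type 1 cell genes, of the flat cells of gas exchange, went the other way, with 17 of 18 above 0, Timp3 up by 1.27 (SE 0.144, adjusted p = 0.0157), 8 higher adjusted over the list alone, and Ager, the usual type 1 marker, at 0.36 (median 0.54, camera adjusted p = 8.54e-05, adjusted p = 0.406 with an estimated correlation). The Ager value is that of its brightest probe, and its dimmer probes stood further apart. On 1 of them the level was 6.12 and 6.06 in LL against 5.37 and 5.4 in WW, and on another 2.28 and 2 against 0.23 and 0.42. The basal cell keratin Krt14 rose by 2.78 (SE 0.372), in a list of 7 that passed at an adjusted p of 0.0263 (adjusted p = 0.549 with an estimated correlation; without WW replicate 1 the first value was 0.14, and without either WL array 0.0754). All 25 genes of the alveolar transitional state, the keratin-rich state between type 2 and type 1 cells, were above 0, and none passed alone: S100a6 was at 2.07 and Krt19 at 2.45 (median 1.62, camera adjusted p = 3.42e-06, adjusted p = 0.629 with an estimated correlation). The WL mice differed in both genes (6.25 and 7.81 for S100a6, 3.76 and 5.89 for Krt19), and that spread enters the test of LL against WW. The 14 club and secretory cell genes had a median of -0.08 (adjusted p = 0.83), and Scgb1a1 was at -0.14.

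Among 63 growth factors, pleiotrophin (Ptn) rose by 1.64 (SE 0.243, adjusted p = 0.0289) and Vegfc, a lymphatic growth factor, by 0.89 (SE 0.149, adjusted p = 0.0401), and the other 61 did not pass. Hbegf, which codes for the protein that the toxin uses as its receptor in species sensitive to it, was at 1.82 (SE 0.499, adjusted p = 0.108), with 4.06 ± 0.09 (SD) in LL and 2.24 ± 0.09 in WW. Its SE also takes in the spread of the WL mice, which were at 2.39 and 4.09. A gene whose WL mice differ can thus fail to pass although its LL and WW mice do not overlap. The growth factor list did not pass (median 0.30, adjusted p = 0.176), nor did the 36 lung injury biomarkers (median 0.69, adjusted p = 0.0697), of which the protein C receptor Procr (1.44, adjusted p = 0.0687) and the adhesion molecule Icam1 (1.34, adjusted p = 0.0968) had the smallest p. The chemokine Ccl20 rose by 2.89 (SE 0.515) while the monocyte chemokine Ccl8 fell by 3.93 (SE 0.518), and the list of inflammatory cytokines and chemokines did not pass (adjusted p = 0.297). Of 26 acute phase genes only complement factor B (Cfb) passed, up by 2.27 (SE 0.398), with 7 higher adjusted over the list alone (median 2.13, camera adjusted p = 2.34e-06, adjusted p = 0.549 with an estimated correlation). Complement genes divided, 2 up and 5 down of 16, and the list did not pass camera (adjusted p = 0.353) but passed fry (adjusted p = 0.0278).

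In all, 808 of 25830 genes passed between LL and WW, 313 higher and 495 lower, and 22 of 41 lists (10 higher, 12 lower). None of the 22 passed with an estimated correlation, and 9 lists passed fry, complement among them. The count of genes rested on the arrays in the model. It was 4 without LL replicate 1, 202 without LL replicate 2, 246 without either LW array, 4 without WW replicate 1 and 20 without WW replicate 2. Without either or both of the WL arrays, whose spread enters the error of every gene, it was 8286, and all 808 genes were among these, but the balance turned, with 4471 higher and 3815 lower. On the LL and WW arrays alone it was 6245, with 3326 higher and 2919 lower. The count was 400 with no detection filter and 447 with the replicate number as a block.

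**Figure D2:**
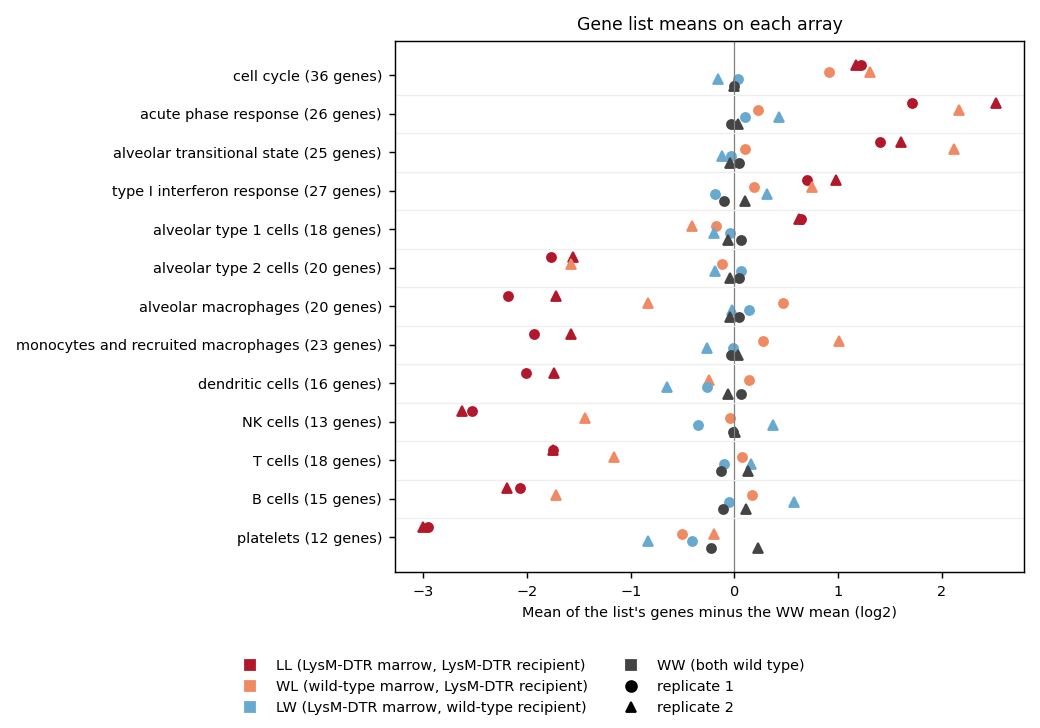
Mean of the genes of 13 lists on each array, as the log2 difference from the WW mean (horizontal axis), coloured by group, with circles for replicate 1 and triangles for replicate 2. Cell cycle means are 0.91 to 1.31 on the LL and WL arrays, and alveolar type 2 cell means are -1.77 and -1.56 in LL but -0.12 and -1.58 in the WL mice.

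WL against WW asks what follows when the receptor is in the recipient and the marrow is wild type. Cell cycle genes rose in both WL mice: the list mean was 0.91 above WW in replicate 1 and 1.31 in replicate 2, 34 of 36 genes were above 0, and 31 rose adjusted over the list alone, though none over all genes. The mitotic activator Cdc20 was at 1.61 (SE 0.143, adjusted p = 0.107) and the spindle midzone gene Prc1 at 1.41 (SE 0.167, adjusted p = 0.248). The list passed camera (median 1.18, adjusted p = 2.46e-32, adjusted p = 0.607 with an estimated correlation, 0.0499 with fry). Without WL replicate 2, which leaves 1 WL array, its median was 1.02. The complement subunit C1qb was at 1.22 (SE 0.239, adjusted p = 0.36), and C1qa had a mean of 1.99 ± 0.32 (SD) against 0.89 ± 0.14 in WW. Of 23 genes of monocytes and recruited macrophages, 3 rose adjusted over the list alone (median 0.41, camera adjusted p = 4.45e-05, adjusted p = 0.607 with an estimated correlation). Their list mean was 0.28 above WW in WL replicate 1 and 1.01 in replicate 2.

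Other lists differed between the WL mice. The alveolar type 2 list mean was -0.12 in WL replicate 1 and -1.58 in replicate 2, and that of the transitional state 0.10 and 2.12. Both lists passed camera, at an adjusted p of 0.000204 and 3.71e-07, but not without WL replicate 2 (0.116 and 0.133). Against the WW mean Sftpc was at -0.21 in replicate 1 and -2.17 in replicate 2, and Lyz2 at -0.37 and -1.71 (adjusted p = 0.486 for the WL mean). The means of B, T and NK cell genes were 0.17, 0.07 and -0.04 in replicate 1 and -1.72, -1.16 and -1.44 in replicate 2, and the acute phase means 0.23 and 2.17. Those 4 lists passed camera and did not without WL replicate 2 (0.252, 0.186, 0.895 and 0.0899). With an estimated correlation the adjusted p was 0.607 for each of these lists.

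Over all genes 1 of 25830 passed between WL and WW, the predicted gene Gm3120, at least 3.01-fold lower in WL; 2112 genes had an unadjusted p under 0.05. Its probe, on chromosome 6, was above background on the WW arrays alone. The count was 0 without either LL array or either LW array. Without a WL or WW array 1 mouse is left in that group, so the count then rests on no spread between its mice. Of 41 lists 21 passed, 13 higher and 8 lower, 8 of the 21 kept their call and direction without WL replicate 2, and none passed with an estimated correlation.

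LW against WW asks the same of receptor in the marrow alone. Lyz2 was at -0.15 (SE 0.408, adjusted p = 1), C1qa had the same mean in both groups (0.89, SD 0.30 in LW and 0.14 in WW), and the cell cycle list had a median of -0.03 (adjusted p = 0.533). The medians of the alveolar type 2 cell, alveolar macrophage, T cell and NK cell lists lay between -0.06 and 0.02. Neutrophils (median -0.23, 16 of 22 genes below 0, adjusted p = 0.102), monocytes and recruited macrophages (-0.13, 19 of 23 below 0, 0.168) and B cells (0.26, 14 of 15 above 0, 0.0567) lay further out without passing. The 4 lists that passed camera were lower: platelets (median -0.65, adjusted p = 4.42e-08), with Gp1bb at -0.63 and Gp5 at -0.89, cardiac muscle (-0.49, 4.75e-09), dendritic cells (-0.35, 0.009) and the unfolded protein response (-0.17, 0.000113). No gene of these lists passed, the adjusted p was 0.623 or 0.811 with an estimated correlation, and the dendritic cell call was lost without LW replicate 2 or WW replicate 1 (0.0999 and 0.174) and that of the unfolded protein response without WW replicate 1 (0.139). The one direction did not hold in other settings: 10 of 14 lists were higher with another background correction and 8 of 16 without LW replicate 1. Cardiac muscle was lower in WL as well (median -0.84, adjusted p = 3.23e-06, adjusted p = 0.607 with an estimated correlation) and in LL, with list means of -0.29 to -0.91 on the 6 arrays against -0.07 and 0.07 in WW, the pair that the 3 comparisons share.

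Among single genes 14 passed between LW and WW, 12 higher and 2 lower. The aldo-keto reductase Akr1c20 and the cytochrome P450 gene Cyp2c50, both of liver-type metabolism, were at least 7.85-fold and 6.87-fold higher, and the ectodysplasin receptor adaptor Edaradd at least 2.07-fold. Each was at background on the LL, WL and WW arrays. Of the 14, 13 were above background on exactly 2 arrays. The other probes of 5 of them were above background on 0 or 1 arrays and could not show a change. Albumin, a liver gene chosen after its values were seen, was at 3.84 in LW replicate 2, -1.92 in LW replicate 1 and -3.66 and -4.45 in the WW mice. The count was 0 with another background correction, on probes above background on all arrays, with another variance model, on the LW and WW arrays alone, and without either LL array, LW replicate 2 or WW replicate 1. It was 1 with the replicate block, 8 without LW replicate 1, 5 without WW replicate 2, 2 without either or both WL arrays, 6 with no detection filter and 7 with the percentile over detected probes.

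The direct comparison of WL with LW, the chimeras with the receptor on one side only, gave Cdc20, higher by 1.64 in WL (SE 0.143, adjusted p = 0.045), as the 1 higher gene, with 1.79 and 2.01 in the WL mice against 0.22 and 0.30 in the LW mice. Another 11 genes were lower in WL, none of which the naming rule covers. On probes above background on all arrays 0 genes passed, so the limit given for LW against WW applies here too. Akr1c20, called there, was at -1.63 and -2.15 in LW and -7.42 and -7.66 in WL, and Cyp2c50 at -2.28 and -1.89 against -7.26 and -7.50. How many of the 11 rest on such probes was not tested, so they are not read as genes lowered by the recipient genotype. Of 36 cell cycle genes 35 were above 0 and 32 rose adjusted over the list alone (median 1.27, camera adjusted p = 1.76e-31, adjusted p = 0.565 with an estimated correlation, 0.0384 with fry). Monocyte and recruited macrophage genes were higher too (median 0.83, camera adjusted p = 1.61e-06, adjusted p = 0.565 with an estimated correlation), with C1qb at 1.34 (SE 0.239). Of the 22 lists that passed, 9 kept their call and direction without WL replicate 2. The 12 genes became 0 without either LL array. Without a WL or LW array 1 mouse is left in that group, so the count then rests on no spread between its mice. Cdc20 kept its call in no model that leaves out an array and still holds 2 mice in both WL and LW. Its call also ended with another background correction, no filter, detection on all arrays, the mean of probes, the replicate block, another variance model, and on the WL and LW arrays alone.

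**Figure D3:**
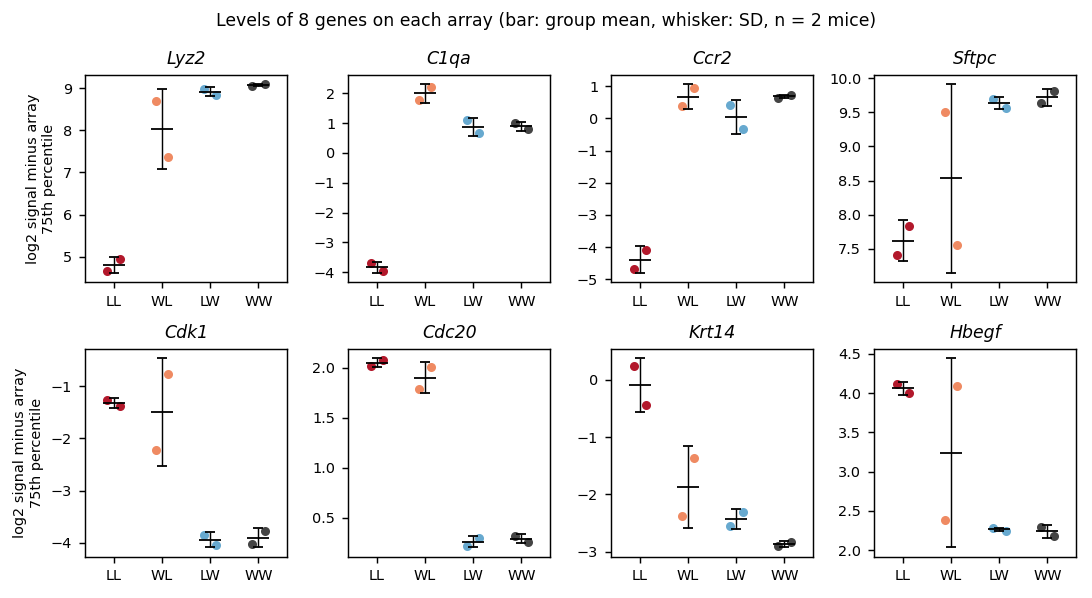
Level of 8 genes on each array (points; log2 signal minus the array's 75th percentile, vertical axis, with its own range in each panel), with group means (bars) and SD (whiskers, n = 2 mice). C1qa lies at -3.84 in LL and at 0.89 to 1.99 in the other groups, and Cdc20 at 2.05 and 1.90 in LL and WL against 0.26 and 0.29 in LW and WW.

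LL against WL adds the receptor in the marrow to LysM-DTR recipients. Clec7a fell by 6.24 (SE 0.363, adjusted p = 0.00516), C1qc by 5.84, C1qa by 5.83 (SE 0.236, adjusted p = 0.00259), Ccr2 by 5.05 and the signal regulatory receptor Sirpb1b fell by 4.87. Higher in LL were the stefin Stfa3 (4.90, SE 0.752), the calcitonin gene-related peptide gene Calcb (3.21, SE 0.28, adjusted p = 0.00986), Fam3b (2.92), Vpreb2 (2.51) and Akr1c14 (2.35). In all 445 genes passed, 148 higher and 297 lower. The excess of lower genes did not hold without WL replicate 1 (1294 higher, 1171 lower) or 2 (2782 higher, 2310 lower). The count was 23 and 195 without LL replicate 1 and 2, 2465 and 5092 without WL replicate 1 and 2, 125 without either LW array, 139 without either WW array, 272 with the replicate block and 0 on the LL and WL arrays alone.

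The effect of the donor genotype itself differed by recipient. The interaction passed for 16 genes, 1 higher and 15 lower. For C1qa the donor effect was -5.83 in LysM-DTR recipients (LL minus WL) and -0.01 in wild-type recipients (LW minus WW), a difference of -5.82 (SE 0.333, adjusted p = 0.0216); Clec7a, C1qc, C1qb and the adaptor Scimp followed the same course. The count was 2209 and 223 without WL replicate 2 and 1, where the excess of lower genes did not hold (1199 higher and 1010 lower, and 126 higher and 97 lower). It was 10 without LL replicate 2, 1 without either LW array and 0 without LL replicate 1 or either WW array; it was 53 with quantile normalisation, 10 with another background correction, 8 on probes above background on all arrays, 2 with the replicate block and 1 with no detection filter.

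Averaged over donors, the recipient genotype changed 327 genes, 162 higher and 165 lower in LysM-DTR recipients (4 against 4 arrays). Cdk1 rose by 2.52 (SE 0.312, adjusted p = 0.0303), Spc24 by 2.40, the mitotic genes Aunip and Pbk by 2.23 and 2.21, and Ect2 by 2.15. Lyz2 fell by 2.58 (SE 0.289, adjusted p = 0.0258), Lyz1 by 2.83, the transcription factor gene Atf7 by 2.95, Traf3ip3 by 2.10 and Zan by 2.04. These averages join unlike arrays: against the WW mean Lyz2 was at -4.40 and -4.13 in the LL mice and -0.37 and -1.71 in the WL mice, and Atf7 at -4.46 and -4.44 against -0.67 and -2.63. Cdk1 was at 2.65 and 2.52 in LL and 1.69 and 3.14 in WL. The count was 12512 and 3429 without WL replicate 1 and 2, 11 without WW replicate 2 and 0 without any other array; it was 126 with another background correction, 98 with no filter and 131 with the replicate block.

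Averaged over recipients, the donor genotype changed 82 genes, 25 higher and 57 lower with LysM-DTR marrow. The lysosomal protease Ctss, abundant in macrophages, fell by 2.61 (SE 0.221, adjusted p = 0.0221), thromboxane synthase (Tbxas1) by 2.29, the haematopoietic cytoskeleton gene Nckap1l by 1.81, Pld4 by 1.77 and the platelet lipoxygenase Alox12 by 1.75. Nkx6-2, Gdf2 and Tbx18 rose by 1.24, 1.12 and 1.08. The balance varied, with 3 higher and 45 lower with another background correction, 8 and 74 without LL replicate 2 and 1029 and 1160 without WL replicate 2. The means of Ctss were 0.72 in LL, 5.54 in WL, 4.64 in LW and 5.04 in WW. The count was 2189 and 474 without WL replicate 2 and 1, 82 without LL replicate 2 (34 of them the same genes), 34 and 1 without LW replicate 1 and 2, and 0 without LL replicate 1 or either WW array; it was 48 with another background correction, 42 on probes above background on all arrays, 22 with the replicate block and 9 with no filter.

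Few calls were shared between the comparisons with WW: 1 gene between WL and LW, 1 between WL and LL and 2 between LW and LL, all lower. They were Gm3120 in each pair and CF550758, chosen after its values were seen, in the last. Independent draws would give 0, 0.019 and 0.038 shared lower genes, and 50 simulated sets of unchanged groups against a common simulated WW pair gave a mean of 0.02, 0 and 0. The WW values were simulated too, so genes lit on the real WW pair alone are not reproduced. The simulated means are therefore no expectation for the real WW arrays. The comparisons share both WW arrays, which are too few to divide, and both shared genes lay at -6.49 or lower on the 6 other arrays, so these calls rest on the signal of the WW pair. Across genes the changes correlated at r = 0.23, 0.64 and 0.20. Simulated unchanged groups that share their controls gave 0.50 for each pair of comparisons. That is the value that groups of equal spread give whatever the data. The spread was not equal here, since the WL mice differed more from each other than the mice of the other groups. The r values therefore cannot be read against 0.50, and no conclusion is drawn from them.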

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

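The tests of the WL mice, of isolated bright spots and of the replicate numbers were chosen after the results they concern were seen; those of liver RNA and of other splits of the arrays were fixed before.

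The donor effect differed between LysM-DTR and wild-type recipients, by a test of that difference, for 16 genes. For the 5 named among them, which macrophages express, the difference was -5.98 for Clec7a (SE 0.513, adjusted p = 0.0433 by limma), -5.82 for C1qa (SE 0.333, 0.0216), -5.71 for C1qc (SE 0.39, 0.0314), -4.44 for C1qb (SE 0.338, 0.0348) and -3.58 for Scimp (SE 0.259, 0.0314). In LysM-DTR recipients the donor effect was -6.24, -5.83, -5.84, -4.57 and -3.68, and in wild-type recipients -0.27, -0.01, -0.13, -0.12 and -0.10.

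The WL mice stood apart from each other, at r = 0.96 against at least 0.99 in the other groups. A poor array or scaling of WL replicate 2 would carry no genotype pattern, but its difference from replicate 1 followed the LL minus LW difference across genes at r = 0.66. A swap of WL replicate 1 with an LW or WW array needs a partner out of place, and 0 of those 4 arrays were closer to the LL mean than to the others. A displaced WL mouse that does not resemble LL would give 0 as well, so this test cannot exclude a swap. In its cell cycle genes replicate 1 was unlike a wild-type recipient under a wrong label, since 35 of the 36 lay above all 4 LW and WW arrays. Across all genes its difference from the WW mean did not follow the LL minus LW difference (r = 0.02, against 0.64 for replicate 2). A wrong label is thus argued against by that list alone, in 1 mouse. A sample from outside the series, or mice that differed in toxin dose, engraftment or response, stay open. The labels divide the WL mice into no groups, so no biological explanation was tested.

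The 14 genes called between LW and WW may rest on isolated bright spots. Probes brighter on exactly 2 arrays than on the other 6, by over 2.5 on the log2 scale, numbered 13 on the LW pair but 17 on LW replicate 2 with WW replicate 1, a pair that shares no group; probes lit on 1 array alone numbered 159, 143, 215 and 71 on the LW and WW arrays and 9, 15, 17 and 44 on the LL and WL arrays. Liver RNA was tested with 20 hepatocyte genes, 12 of them measured, of which Fga and Hpx are also acute phase genes: the median LW minus WW difference was 0.49, under the bound of 0.5 set beforehand, but by less than the spread of 1.71 over the genes. That a bound must be passed by more than the spread was applied once the value was known, so liver RNA is left open. In LW replicate 2 alone albumin (3.84) and Serpina1a (4.24) were high, against -1.92 and -1.40 in LW replicate 1.

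Neutrophil genes were higher in replicate 2 than in replicate 1 of all 4 groups, with list means of -0.53 and 0.97 in LL, -0.85 and 0.36 in WL, -0.69 and -0.11 in LW and -0.23 and 0.23 in WW; of 22587 genes above background on all arrays 27, of which 9 are in the neutrophil list, lay more than 0.3 above the group mean in replicate 2 of every group, against 1 in replicate 1. More blood left in the replicate 2 lungs would raise red cell genes too, but the erythroid mean was higher in replicate 2 in 2 of 4 groups, with differences of 2.33, -0.94, -0.64 and 0.06. A shared day or batch that the number marks was not decided: the order in 4 of 4 groups is the pattern itself, and its 8 relative orders are too few for a share under 0.05. The design names no biological difference between the replicates, so none was tested.

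With the 8 arrays compared 4 against 4 in a model of these groups alone, 171 genes were called for the recipient genotype. Of 35 splits 1 gave as many, the real one, and the highest other, LL with WL replicate 2 and WW replicate 2, gave 2. That share met the bound of under 0.05 set beforehand, but 1 of 35 is the smallest it can be. The 2 arrays of a group are also alike in any split, so neither chance nor the slide column is excluded. For the donor genotype the same model called 0 genes (82 in the model of 4 groups), so all 35 of 35 splits gave as many whatever they called, and the test decides nothing about the donor; the highest was the 171 of the recipient split, which points to a structure of the samples.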

How the results depend on the processing

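The settings without both WL arrays and without population outlier spots were chosen after the data were seen, the others before. Counts are given in the order WL, LW and LL against WW, WL against LW, LL against WL, recipient, donor and interaction, and were 1, 14, 808, 12, 445, 327, 82 and 16. Within 1.5 times of these, in all 8, were the deposited series table, the fold threshold, the mean of probes (for genes) and the removal of population outlier spots; no gene called in both changed direction under any setting. With normexp background correction the counts were 0, 0, 600, 0, 471, 126, 48 and 10. With no detection filter, which tests 37074 genes, they were 0, 6, 400, 5, 255, 98, 9 and 1, and on genes above background on all arrays (22598) 0, 0, 648, 0, 380, 265, 42 and 8. With the replicate number as a block they were 0, 1, 447, 5, 272, 131, 22 and 2. The replicate differences of LL and WL correlated across genes at r = 0.23, and those of the other pairs of groups at -0.11 to 0.06. Same-numbered mice thus varied together weakly in LL and WL and not across all 4 groups. A batch that touches few genes is left open. With trend and robust variances WL, LW and WL against LW gave 0. Quantile normalisation moved the interaction to 53, and the percentile over detected probes moved LW to 7. On the compared arrays alone WL, LW, WL against LW and LL against WL gave 0 and LL gave 6245. Without both WL arrays LW gave 2 and LL 8286. For the counts that moved, the cause was not tested. A block for the slide gives no value, as all arrays are on 1 slide.

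Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, the counts ran from 0 to 9741 for WL, 0 to 8 for LW, 4 to 8286 for LL, 0 to 9651 for WL against LW, 23 to 5092 for LL against WL, 0 to 12512 for the recipient, 0 to 2189 for the donor and 0 to 2209 for the interaction. The high ends came from leaving out a WL array, apart from LW, whose 8 came without LW replicate 1. Shared calls ran from 0 to 3 for WL and LW, 0 to 5623 for WL and LL and 0 to 3 for LW and LL. Shared calls of WL and LW and of WL and LL, 1 each, were 0 with normexp, no filter, detection on all arrays, the block, trend and robust variances and the compared arrays alone; those of LW and LL, 2, were 0 in these except 1 with no filter, and 1 with the percentile over detected probes and without both WL arrays.

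Of 66 named genes called in LL, 66 kept their call with the series table, on the compared arrays and without both WL arrays, 50 with normexp, 43 with the block and 41 with no filter, against 3 and 18 without LL replicate 1 and 2, 24 without either LW array, and 1 and 5 without WW replicate 1 and 2. Of 49 named genes not called in LL, 41 were called without either or both WL arrays and 34 on the compared arrays. Edaradd turned from higher to lower in LW with no filter (-0.18), where another of its probes is used. The 5 named interaction genes all kept their call without either WL array, 2 of them without LL replicate 2, and 0 without any other array, with the block or with no filter.

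Lists called, 21 for WL, 4 for LW, 22 for LL and 22 for WL against LW, were 0 in each with an estimated correlation and 1, 0, 9 and 1 with fry. For LW they were 14 with normexp, 9 on genes above background on all arrays, 7 with the mean of probes, 8 with the block and 10 on the compared arrays; the other settings kept all 4 counts within 1.5 times. Without 1 array they ran from 16 to 24, 4 to 16, 21 to 27 and 15 to 24. Without WL replicate 2 the direction of camera's test turned in WL for ciliated cells (median -0.01, against -0.89 without replicate 1), T cells (0.11 and -1.29), B cells (0.18 and -1.88) and fatty acid and surfactant lipid synthesis (0.02 and -0.78). In WL against LW it turned for ciliated cells (0.02, against -0.90 without replicate 1), alveolar macrophages (0.38 and -0.91), T cells (-0.03 and -1.39) and fatty acid and surfactant lipid synthesis (0.02 and -0.65). Erythroid cells in LL turned without LL replicate 1 (0.67, adjusted p = 0.0129), and were at -1.66 without LL replicate 2. A change of sign in values that passed under neither setting was not counted as a reversal.

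The median of all genes in WL was at -0.05, at -0.126 with normexp and at -0.161 with no filter, so the scaling did not remove every overall shift. Genes near background limit the bounds given for fold changes, and 66.3 to 72.3% of spots were well above it.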

Other observations

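The test of genes near Lyz2 was fixed before its result was seen; the ligands of the epidermal growth factor receptor were chosen after their values were seen.

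Further groups of genes moved in LL against WW. All 8 mesothelial cell genes, of the pleural lining, were above 0, and Wt1, its transcription factor, rose by 1.83 (SE 0.172, adjusted p = 0.0122 by limma; list median 0.93, camera adjusted p = 0.00102, adjusted p = 0.526 with an estimated correlation). Type I interferon response genes were above 0 in 26 of 27, none passed over all genes and 15 did adjusted over the list alone, with Ifit2 at 0.87 and Xaf1 at 1.01 (median 0.87, camera adjusted p = 6.27e-07, adjusted p = 0.549 with an estimated correlation). The 17 genes of ciliated cells were all below 0 and none passed (median -0.76, camera adjusted p = 1.52e-05, adjusted p = 0.565 with an estimated correlation). Of 30 extracellular matrix genes Thbs2 alone passed, at least 1.84-fold higher (median 0.80, camera adjusted p = 0.00132, adjusted p = 0.629 with an estimated correlation). Glucocorticoid and clock genes were higher (median 0.86, 0.00339, adjusted p = 0.526 with an estimated correlation), with none passing alone. Of the genes of alternative macrophage activation 5 of 17 fell, Cd163 at least 9.30-fold and Folr2, above background on 1 of 2 LL arrays, by 3.47 (list adjusted p = 0.00354, but 0.0943 without either WL array; adjusted p = 0.549 with an estimated correlation). Of 24 genes of fatty acid and surfactant lipid synthesis, Fabp5, a fatty acid binding protein of macrophages and epithelium, fell by 2.77 and the factor Cebpa fell by 1.69 (list adjusted p = 0.00854, adjusted p = 0.629 with an estimated correlation). The p53 target list (median 0.37, 0.00984) lost its call without LL replicate 2 (0.0503) or WW replicate 2 (0.0868), and cardiac muscle (-0.38, 0.0108) without LL replicate 2 (0.0611); with an estimated correlation both had an adjusted p = 0.629.

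Structural cells moved little as lists in LL: the adjusted p was 0.75 for endothelial cells (median 0.10), 0.57 for fibroblasts (0.04) and 0.916 for smooth muscle and pericytes (0.10). The adjusted p was 0.725 for hypoxia, 0.144 for NRF2 and oxidative stress, 0.338 for the unfolded protein response, 0.176 for heat shock and immediate early genes, 0.604 for cholesterol synthesis, 0.702 for adipocytes and for erythroid cells, 0.284 for plasma cells and 0.176 for mast cells, basophils and eosinophils, of which the tryptase Tpsb2 rose by 1.95 (SE 0.272). Erythroid genes differed between the LL mice, with list means of -1.52 and 0.82. Of the ligands of the epidermal growth factor receptor none passed: Ereg was at 5.49 (adjusted p = 0.193), Areg at 2.76 (adjusted p = 0.0943), Hbegf at 1.82, Tgfa at 0.09, Egf at -0.12, Btc at -0.15 and Epgn, above background on 4 of 8 arrays, at -0.40. The spread of the WL mice enters these tests, and they were at 2.39 and 4.09 for Hbegf and at -0.70 and 1.64 for Areg.

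All mice are labelled male, and Xist, the RNA that coats the inactive X chromosome of female cells, was above background on all WL, LW and WW arrays and on neither LL array: its level was -6.02 and -5.40 in LL, -2.35 and -3.25 in WL, -4.02 and -3.67 in LW and -2.92 and -2.84 in WW, at least 4.82-fold lower in LL than in WW (adjusted p = 0.0187 by limma). The Y-linked gene Ddx3y was above background on all 8 arrays and at 0.31 (adjusted p = 0.297). The sex of the marrow donors is not in the labels.

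If the receptor gene sits at Lyz2, which the labels do not say, strain variants linked to it may differ between LysM-DTR and wild-type recipients and could appear as changes near it. Of 148 genes with a probe within 10 Mb of Lyz2 on chromosome 10 (mm9), Lyz1 and Lyz2 left out, 2 were called between LL and WW, against 800 of 25535 elsewhere, an odds ratio of 0.42 (95% confidence interval 0.05 to 1.56; Fisher's exact test, two-sided, p = 0.337). No excess was seen, which met the bound set beforehand, but the interval includes 1, so a small excess is left open; that reading was made once the value was known.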
